A study of Mus musculus with 12 samples.

How the data were processed

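The series table analysed here lists 54537 genes in 12 libraries of poly(A) RNA from mouse ES cells and embryoid bodies. Libraries were made with the NEBNext Ultra II kit and sequenced on an Illumina instrument, per the labels. The deposited values are FPKM per gene as the authors computed them. The submitters' processing notes name Cufflinks 2.1.1 and the GRCm38 (mm10) genome; the aligner, the annotation and any filter are not given in the sources used here. Gene identifiers matched GENCODE M21 for 99.9% of genes, and coordinates were equal for 98.6%, so GRCm38 coordinates are given as in the file, counted from 1. The table has an exact 0 in some library for 17 of 6620 genes with a median of at least 10 FPKM, so a 0 can be a failed estimate and such genes are said to be listed at 0. FPKM depends on an estimated split of reads among overlapping or near-identical genes, and on the share of RNA taken by other genes.

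Groups were taken from the titles and genotype and time labels: WT and the line labelled WT+1343KO-a14, at days 0, 8 and 16, with 2 libraries each. Nothing says that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. The 1343KO line is 1 clone. Depth is not given. It was estimated from genes whose FPKM are whole multiples of a smallest step, for 1 to 3 fragments, transcripts of at least 1500 nt and an assumed 200 nt fragment, with 81.1% to 85.4% of values within 5% of a whole number; this gave about 4885000 to 8047000 fragments per library. The estimate is approximate, and no count test was run on it.

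Genes with at least 1 FPKM in at least 2 libraries were tested (16289). A linear model of log2(FPKM + 1) with 1 mean per group was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with a trend in the empirical Bayes variance and 6 residual degrees of freedom. There were 10 contrasts: the lines at each day and over all days, each line's change from day 0 to days 8 and 16, and the difference between those changes. P-values are two-sided and adjusted by Benjamini-Hochberg within each contrast, and a gene passed at an adjusted p under 0.05. With 2 against 2 libraries an exact permutation test cannot go below p = 0.333, so the calls rest on the spread pooled across genes and groups. Lists of genes were tested with camera in limma at a preset correlation of 0.01, and again with an estimated correlation; adjusted p for a list is over the lists of that contrast. The 40 lists held 708 entries, 696 of them in the table, with some genes in more than 1 list, and 39 lists had the minimum of 5 tested genes. Counts of list members are adjusted over all genes tested, and the count adjusted over the list alone is given where it differs.

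The groups, contrasts, tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule took the genes at the locus named by the title; the 10 genes with the largest change in each direction among those that passed with no overlap between the groups' libraries, leaving out unnamed gene models and small RNAs; 20 fixed lineage and pluripotency markers whatever their p, of which Tubb3 is not in the table; and list members, of which the text takes the called ones with the smallest p. The condition of no overlap was not applied to the contrast over all days or to the differences between changes. The text names part of the genes so chosen. Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-of-ratios and TPM scaling, the replicate number as a block, robust empirical Bayes, a minimum log2 change of 1, each day's 4 libraries alone, an estimated correlation, and each library left out in turn; leaving out chromosomes 8 and Y was added after seeing the data. The scripts were tested on simulated data made from day 0 (1343KO against WT, 16289 genes, 200 changed): 65% of 2-fold and 87% of 4-fold changes were recovered, 4.40% of calls were false, and 6 of 200 unchanged lists had p under 0.05. Noise in the simulation was normal and independent between genes, so these rates do not cover correlated genes or differences between cultures. Each gene had the same spread in all groups, so the rates do not test that assumption of the fit. Simulated changes were set on the log2(FPKM + 1) scale in genes above 1 on it in WT at day 0, and falls were stopped at 0. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Knockouts of other noncoding RNAs, the reads and snoRNA levels were not analysed here.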

Results

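RNA was measured in mouse embryonic stem (ES) cells and in the embryoid bodies grown from them, for a wild type line (WT) and a line labelled WT+1343KO-a14, called the 1343KO line here. ES cells were sampled in serum with leukaemia inhibitory factor, a cytokine that keeps them undifferentiated (day 0), and after 8 and 16 days as floating aggregates without it. Each of the 6 groups had 2 libraries, 12 in all. The series concerns knockouts of long noncoding RNAs in ES cells, and its title links the small nucleolar RNA SNORA73 with leaving pluripotency, so the comparisons ask how the lines differed as ES cells and on the path out of pluripotency. Depth recovered from the lowest values was about 4885000 to 8047000 fragments per library, with the shallowest at 0.607 of the deepest. Between 12909 and 14069 genes per library reached 1 FPKM, a level scaled to transcript length and depth. Values below are mean FPKM ± SD over 2 libraries unless said otherwise, and changes are on the log2(FPKM + 1) scale, which understates changes of low genes.

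Replicates correlated at 0.970 to 0.975 across genes (genes are not independent replicates). WT day 0 and WT day 16 libraries correlated at 0.767 on average. The 1343KO libraries of day 16 correlated with WT day 0 libraries at 0.930 and with WT day 16 libraries at 0.827. In a principal component analysis the first component held 58.8% of the variance and the second 11.7%.

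**Figure D1:**
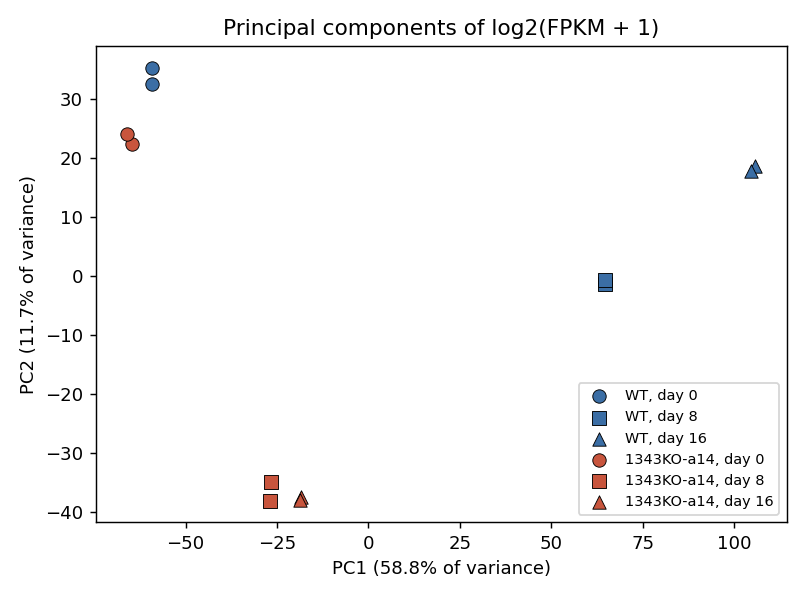
Principal component 1 (58.8% of variance) against principal component 2 (11.7%) for the 12 libraries, with colour giving the genotype, marker shape the day, and each point 1 library. WT libraries of days 8 and 16 lie apart from those of day 0 along component 1, and the 1343KO libraries of all 3 days lie nearer to WT day 0 along it.

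The labels do not say which gene the number in the line's name stands for, nor whether the leading WT+ names the parental line or a rescue, so the comparisons are between 2 labelled lines. In mouse the SNORA73 copies Snora73a and Snora73b lie in Snhg3 (ENSMUSG00000085241), a noncoding snoRNA host gene on chromosome 4, 132348014 to 132353686 of GRCm38. Snhg3 was listed at 61.1 and 47.0 FPKM in the WT day 0 libraries, 13.7 and 30.2 at day 8, and 16.7 and 8.31 at day 16. In the 1343KO line it was listed at 1.57 and 0 at day 0, and at 0 or 1.1e-242 in the 4 later libraries. The difference passed at day 0 (log2 change -5.09 ± 0.49 (SE), adjusted p = 0.000738), day 8 (adjusted p = 9.36e-05) and day 16 (adjusted p = 0.000183). Snora73a (ENSMUSG00000064387, 132352775 to 132352979) was listed at 11.2 in 1 WT day 0 library, 10.7 in 1 1343KO day 8 library and 0 in the other 10, and Snora73b (ENSMUSG00000065353, 132352322 to 132352526) did not exceed 1.3e-24 in any. Poly(A) selection misses snoRNAs, so these values say nothing of snoRNA levels. Rcc1 (ENSMUSG00000028896, 132331919 to 132353605), which encodes a chromatin-bound exchange factor for the GTPase Ran, overlaps Snhg3 on the annotation, so reads can be split between them. Rcc1 in the 1343KO line was at 46.3 ± 3.99 against 82.7 ± 5.02 at day 0 (log2 change -0.82 ± 0.15 (SE), adjusted p = 0.0198), and higher than WT at day 8 (0.70 ± 0.15) and day 16 (1.48 ± 0.15). Its day 0 call ended without any 1 of the 4 day 0 libraries, with adjusted p = 0.0699 (WT replicate 1), 0.13 (WT replicate 2), 0.0547 (1343KO replicate 1) and 0.12 (1343KO replicate 2). The day 8 call ended on the 4 day 8 libraries alone (adjusted p = 0.0735).

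As ES cells, the 1343KO line had lower levels of genes of extraembryonic endoderm, the yolk sac lineage that also shares genes with liver. Of 19 measured members of this list 9 were lower, 0 higher and 10 did not pass (median -0.37, adjusted p = 1.67e-12). Chromosome 8 genes as a whole were also lower, by a median of -0.42, and without chromosomes 8 and Y the list's median was -0.33. Dab2, an endocytic adaptor of that lineage, was at 5.29 ± 0.483 against 48.2 ± 1.3 FPKM (SD, n = 2; log2 change -2.97 ± 0.12 (SE), adjusted p = 9.73e-06). Cubn, an endocytic receptor (-2.75 ± 0.12), and Col4a2, a basement membrane collagen gene on chromosome 8 (-2.24 ± 0.07), were lower. The endoderm transcription factors Gata4 (2.65 ± 0.856 against 21.6 ± 3.11; -2.64 ± 0.18), Gata6 (-2.31 ± 0.31), Sox17 (-2.46 ± 0.45) and Foxa2 (-1.25 ± 0.22) were lower too. In the definitive endoderm list 5 were lower, 2 higher and 8 did not pass (6 lower and 2 higher adjusted over the list alone). That list's median was 0.00, its mean -0.63 and its test direction downward, and it did not pass (adjusted p = 0.122; 0.00754 without 1343KO replicate 2). The call of Sox17 ended without WT replicate 1 (adjusted p = 0.1), WT replicate 2 (0.103) or a filter (0.0576), and that of Foxa2 without WT replicate 2 (0.111), 1343KO replicate 1 (0.0701) or 1343KO replicate 2 (0.0678). The 2 higher members were the epithelial keratins Krt18 (0.83) and Krt8 (0.52). Srgn, a proteoglycan core protein, was also lower (3.61 ± 0.036 against 41.4 ± 0.36; log2 change -3.20 ± 0.30 (SE), adjusted p = 0.000647).

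Zscan4 genes, which mark the 2-cell-like state that ES cells enter briefly, went the other way: 5 of 6 measured members of the 2-cell-like list were higher (median 1.46, adjusted p = 1.96e-07), among them Zscan4b (1.45 ± 0.20) and Zscan4f (1.64 ± 0.24). Members of this family are near-identical, so their levels are uncertain one by one. All 5 calls ended with a pseudocount of 0.1, at adjusted p of 0.0566 for Zscan4b, 0.0732 for Zscan4f, 0.246 for Zscan4c, 0.0969 for Zscan4e and 0.162 for Gm8300, so the count of 5 depended on the pseudocount of 1. The call of Zscan4f also ended without 1343KO replicate 2 (0.0637) or WT replicate 2 (0.069), and that of Gm8300 without 1343KO replicate 1 (0.0823) or WT replicate 2 (0.113). That of Zscan4e ended without 1343KO replicate 1 (0.067) or 2 (0.0533) or WT replicate 2 (0.0815). That of Zscan4c ended with TPM scaling (0.0573) and without any 1 of the 4 day 0 libraries (0.11 and 0.0872 for WT, 0.0878 and 0.0956 for 1343KO). Of 24 targets of the tumour suppressor p53 measured, 6 were higher and 18 did not pass (9 higher and 1 lower adjusted over the list alone; median 0.22, adjusted p = 5.88e-05, and adjusted p = 0.0563 with an estimated correlation), with Perp, a membrane protein of cell death (1.12 ± 0.14), and Ccng1, cyclin G1 (0.51 ± 0.07), in front. Tagln, an actin-binding protein of smooth muscle, was at 28.1 ± 0.432 against 5.61 ± 1.89 (2.17 ± 0.17), and Gpa33, a cell surface antigen, at 27.9 ± 1.21 against 6.04 ± 0.074 (2.04 ± 0.13). Of the naive pluripotency list, Nanog (0.49 ± 0.08) and Dppa3 (1.80 ± 0.33) were higher, Klf5 lower (-0.45 ± 0.10) and 17 did not pass (adjusted p = 0.216 for the list). These 3 calls ended without any 1 of the 4 day 0 libraries, with adjusted p (in the order WT replicates 1 and 2, 1343KO replicates 1 and 2) of 0.0844, 0.0536, 0.0562 and 0.0797 for Nanog, 0.0656, 0.139, 0.0919 and 0.0977 for Dppa3, and 0.118, 0.195, 0.137 and 0.121 for Klf5. That of Klf5 also ended without WT day 8 replicate 1 (0.0573) or 2 (0.0575) or with a replicate block (0.0536). That of Dppa3 ended without a filter (0.0583) or with a pseudocount of 0.1 (0.0599). Pou5f1, the pluripotency factor Oct4, was at 826 ± 35.1 against 762 ± 0.82 (adjusted p = 0.605), and Sox2, its partner, at 187 ± 0.937 against 171 ± 3.95 (adjusted p = 0.477). Zfp42, Esrrb, Klf4, T, Eomes, Fgf5, Afp, Nes, Pax6, Tnnt2, Kdr and Hbb-bh1 did not pass at day 0.

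Y-linked genes and chromosome 8 genes were also lower in the 1343KO line at day 0. Eif2s3y, a translation factor gene on the Y chromosome, was at 0.858 ± 0.599 against 15.2 ± 1.94 at day 0 and was at 0.294 ± 0.12 and 0.359 ± 0.228 at days 8 and 16, where WT had 21.9 ± 1.81 and 20.8 ± 4.54. Ddx3y (-2.54 ± 0.23) and Uty (-2.46 ± 0.19), also Y-linked, were lower at day 0. Among genes with a mean of at least 20 FPKM, the chromosome 8 median of the log2 difference, relative to the other chromosomes, was -0.42 at day 0, -0.41 at day 8 and -0.35 at day 16. The medians of the other 19 chromosomes spanned -0.03 to 0.03 at day 0, -0.22 to 0.09 at day 8 and -0.23 to 0.10 at day 16. Chromosome 8 held 125 of the day 0 calls, 123 of them lower in the 1343KO line. In all, 604 of 16289 genes passed at day 0 (259 higher, 345 lower; limma, Benjamini-Hochberg adjusted p under 0.05), 90 and 104 of them by at least 2-fold. Without chromosomes 8 and Y, a choice made after seeing the data, 407 passed and the share that was higher went from 42.9% to 54.5%. Of 39 lists tested 10 passed, and 2 of them (extraembryonic endoderm and 2-cell-like) held with an estimated correlation. The mitochondrial list was also among the 10 (median 0.20, adjusted p = 1.1e-06, and adjusted p = 0.347 with an estimated correlation), with 1 of 13 measured members higher and 12 not passing (6 higher adjusted over the list alone). Mitochondrial genes held 9.17% and 9.04% of all FPKM in the 1343KO libraries of day 0 and 7.66% and 8.12% in those of WT, and this share can also vary with RNA quality. The count of genes rested on single libraries: 271 passed without WT replicate 1, 203 without WT replicate 2, 335 without 1343KO replicate 1, 231 without 1343KO replicate 2, and 0 by limma on the 4 day 0 libraries alone (2489 at an unadjusted p under 0.05).

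**Figure D2:**
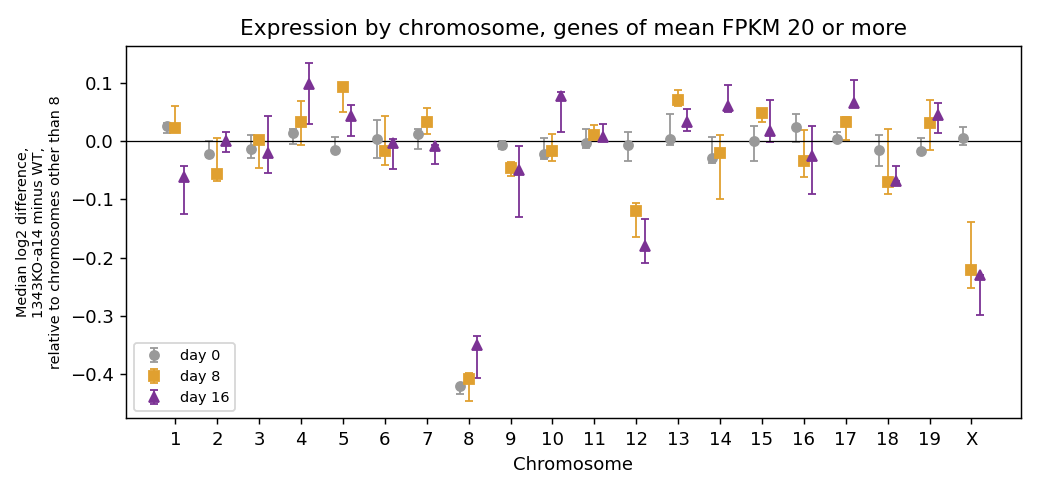
Median log2 difference (1343KO minus WT) of genes with a mean of at least 20 FPKM on each chromosome, relative to the chromosomes other than 8. Colour and marker give the day. Bars run from the point to the lowest and highest value over pairings of single libraries. A bar is left out on a side where that value does not lie beyond the point. Chromosome 8 lies lowest on all 3 days, at -0.42, -0.41 and -0.35.

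In WT, 8 days of embryoid body culture lowered the pluripotency genes and raised yolk sac endoderm, blood and mesoderm genes. Pou5f1 went from 762 ± 0.82 to 35.9 ± 0.401 FPKM (SD, n = 2; log2 change -4.37 ± 0.09 (SE), adjusted p = 4.87e-09), and Tdgf1, a Nodal co-receptor, fell further (-5.08 ± 0.06). In the naive pluripotency list, 19 of 20 measured members fell and 1 did not pass (median -3.36, adjusted p = 1.25e-13), with Nanog (-3.45 ± 0.08), Dppa4 (-3.45) and Zfp42 (-4.24) at the lowest p. Sox2 (-3.11), Esrrb (-4.67) and Klf4 (-3.55) fell as well. Hbb-bh1, an embryonic beta globin, rose from 3.44 ± 0.281 to 802 ± 59.9 (log2 change 7.50 ± 0.41 (SE), adjusted p = 7.19e-07). In the blood list, 14 of 16 measured members rose and 2 did not pass (median 2.52, adjusted p = 1.8e-06). Of the extraembryonic endoderm list 17 of 19 measured members rose and 2 fell (median 2.53, adjusted p = 3.99e-09). Those that rose included Rbp4, a retinol carrier (6.12 ± 0.16), Apob, a lipoprotein (5.78), and Ttr, a thyroid hormone carrier (5.12), and those that fell were the laminin Lama1 (-1.33) and the factor Sox7 (-0.54). The Sox7 call ended without WT day 0 replicate 1 (adjusted p = 0.149) or 2 (0.101), WT day 8 replicate 1 (0.212) or 2 (0.0592), WT day 16 replicate 1 (0.052) or 2 (0.0521), 1343KO day 8 replicate 1 (0.0544) or 2 (0.0543), or 1343KO day 16 replicate 1 (0.0539) or 2 (0.0537). It also ended without a filter (0.0714), with a pseudocount of 0.1 (0.139), with a replicate block (0.0506) and with TPM scaling (0.129). Among general mesoderm genes, 13 of 15 measured members rose, 1 fell and 1 did not pass (median 3.09, adjusted p = 2e-06), led by the transcription factors Hand1 (5.83 ± 0.17) and Snai2 (4.77). Wt1, a kidney and mesothelium factor, fell (-1.03), a call that ended without WT day 0 replicate 2 (adjusted p = 0.0529) or WT day 8 replicate 1 (0.0944). In the endothelial list 12 of 15 measured members rose, 1 fell and 2 did not pass (median 1.75, adjusted p = 7.08e-05), with Flt1 (3.09), Cdh5 (3.47) and the receptor Kdr (3.97) in front and the guidance receptor Robo4 (-2.23) lower. The endoderm factors Gata4 (1.43) and Foxa2 (1.96), the foetal plasma protein Afp (3.87) and cardiac troponin Tnnt2 (3.68) rose, and the eye and brain factor Pax6 fell (-1.08). In the ribosome biogenesis list all 35 measured members fell (median -1.39, adjusted p = 4.84e-18). In total 8352 genes passed, 4364 of them higher, and 23 of 39 lists, of which 11 held with an estimated correlation. At a mean FPKM of at least 5, 2945 were higher and 3173 lower.

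At day 16 in WT, Afp and genes of the fibroblast and macrophage lists were higher than at day 0. Afp reached 8193 ± 75.8 FPKM from 43.1 ± 0.443 (SD, n = 2; log2 change 7.54 ± 0.21 (SE), adjusted p = 8.97e-09), and Col1a1, the main fibrillar collagen, 978 ± 57.5 from 5.42 ± 0.702 (log2 change 7.26 ± 0.15 (SE), adjusted p = 1.68e-09). In the fibroblast and matrix list, 17 of 18 measured members rose and 1 did not pass (median 5.60, adjusted p = 1.89e-11). In the macrophage list all 15 measured members rose (median 4.24, adjusted p = 4.16e-08), among them Mrc1, a mannose receptor (4.12 ± 0.16), and Csf1r, the receptor for the macrophage growth factor (4.69). Pou5f1 was down to 21.1 ± 3.5 (-5.12 ± 0.09), with Zfp42 (-5.21), Nanog (-4.19) and Sox2 (-3.74) also lower; in the naive list, all 20 measured members fell (median -3.62, adjusted p = 3.18e-13). Hbb-bh1 was back at 6.19 ± 1.92 (adjusted p = 0.19 against day 0). Nes, a neural intermediate filament, rose (1.36) and Eomes, a mesendoderm factor, fell (-1.04). In the cell division list all 20 measured members fell (median -1.29, adjusted p = 2.98e-10), with the mitotic kinase Plk1 (-1.97 ± 0.07) in front. In the ribosome biogenesis list all 35 measured members fell (adjusted p = 3.1e-18), led by nucleolin, Ncl (-2.19 ± 0.05). In total 9972 genes passed, 5326 of them higher, and 24 lists, 11 with an estimated correlation. At a mean FPKM of at least 5, 3093 were higher and 3770 lower.

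In the 1343KO line, 8 days of the same culture raised Fgf5 and Otx2, genes of the formative epiblast, the state just after naive pluripotency. Fgf5, a growth factor of that state, went from 0.991 ± 0.439 to 24.4 ± 0.497 FPKM (SD, n = 2; log2 change 3.69 ± 0.22 (SE), adjusted p = 7.74e-06), and Otx2, a head and epiblast factor, rose by 3.45 ± 0.23. In the formative list 6 of 14 measured members rose, 3 fell and 5 did not pass (median 0.49, adjusted p = 0.112), so the list did not pass. Pou5f1 fell by 0.84 to 461 ± 10.8, Klf4, a naive factor, went from 96.9 ± 3.39 to 19.3 ± 1.33 (-2.27 ± 0.15), and Sox2 was at 188 ± 0.029 after 187 ± 0.937 (adjusted p = 0.983). In the naive list, 3 of 20 measured members rose, 10 fell and 7 did not pass (3 rose and 11 fell adjusted over the list alone; median -0.55, adjusted p = 0.000173), led by the imprint regulator Zfp57 (-1.42) and Klf4; Klf2 (0.90) and Dppa3 (2.15) were among those that rose. In the primitive streak list 6 of 8 measured members rose and 2 did not pass (median 1.52, adjusted p = 0.0013), with T, the streak factor brachyury (2.28 ± 0.20), and Fgf8 (2.59) in front. In the trophectoderm list, of the placental lineage, 9 of 13 measured members rose and 4 did not pass (10 rose adjusted over the list alone; median 1.41, adjusted p = 8.65e-06), among them Hand1 (2.34) and Plac1 (2.35). In the definitive endoderm list, 8 of 15 measured members rose and 7 did not pass (9 rose adjusted over the list alone; median 1.39, adjusted p = 6.54e-06), with the epithelial keratins Krt8 (2.78) and Krt18 (3.15) in front. In the 2-cell-like list all 6 measured members fell (median -2.37, adjusted p = 1.66e-07). Hbb-bh1 was at 2.23 ± 1.44 (adjusted p = 0.0952), and in the blood list 1 of 16 members, the blood factor Runx1, rose and 15 did not pass. In total 3828 genes passed, 2441 of them higher (63.8%), a share of 52.6% with median-of-ratios scaling and 53.5% with TPM scaling, and 18 lists, 11 with an estimated correlation. The count was 2483 without 1343KO day 0 replicate 2 and 2480 without 1343KO day 8 replicate 2, and the call of Runx1 ended without 1343KO day 0 replicate 1 (adjusted p = 0.106), day 0 replicate 2 (0.0591) or day 8 replicate 2 (0.146), or without a filter (0.0504).

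By day 16 the 1343KO line had higher heart, placental and streak genes than at day 0. Actc1, cardiac actin, rose from 0.139 ± 0.0329 to 14.6 ± 1.1 FPKM (SD, n = 2; log2 change 3.77 ± 0.18 (SE), adjusted p = 2.28e-06), and in the cardiac list 11 of 18 measured members rose, 1 fell and 6 did not pass (median 1.90, adjusted p = 0.000128, and adjusted p = 0.0521 with an estimated correlation), with Tnnc1, cardiac troponin C, also higher (2.86 ± 0.22) and titin, Ttn, lower (-0.73). The call of Ttn ended without 1343KO day 0 replicate 1 (adjusted p = 0.0808) or 2 (0.112), without 1343KO day 16 replicate 1 (0.1) or 2 (0.086), and with a pseudocount of 0.1 (0.061). In the trophectoderm list, 10 of 13 measured members rose and 3 did not pass (11 rose adjusted over the list alone; median 1.69, adjusted p = 2.59e-06), including the placental prolactin family member Prl3d1 (2.92 ± 0.23). In the streak list 6 of 8 measured members rose and 2 did not pass (6 rose and 1 fell adjusted over the list alone; median 2.22, adjusted p = 0.000449), with T (2.66), Foxa2 (2.34) and Eomes (2.09) among those that rose. In the general mesoderm list, 12 of 15 measured members rose and 3 did not pass (median 1.24, adjusted p = 0.000131), with Hand1 (2.64), Hand2 (2.23) and Pdgfra (1.26) in front, and Kdr rose (1.70). Pou5f1 was at 408 ± 15.4 (log2 change -1.02 ± 0.09 (SE), adjusted p = 7.75e-05), Nanog at 149 ± 13.4 (-0.48 ± 0.08) and Sox2 at 182 ± 13.3 (adjusted p = 0.723). In the naive list, 2 of 20 measured members rose, 13 fell and 5 did not pass (2 rose and 14 fell adjusted over the list alone; median -0.67, adjusted p = 6.03e-08), with Klf4 down to 12.1 ± 0.281 (-2.90 ± 0.15). Afp, at 36.3 ± 9.63, and Hbb-bh1, at 12.5 ± 7.16, did not pass (adjusted p = 0.23 and 0.121); without 1343KO day 0 replicate 2 Afp passed (0.0392), and without 1343KO day 16 replicate 1 Hbb-bh1 passed (0.0385). In the macrophage list 1 rose, Csf1r (1.12), 1 fell, Laptm5 (-2.11), and 13 did not pass. In the ribosome biogenesis list 28 of 35 measured members fell and 7 did not pass (29 fell adjusted over the list alone; median -0.46, adjusted p = 4.04e-16). In total 4368 genes passed, 2967 of them higher (67.9%), and 23 lists, 9 with an estimated correlation. The median over all genes was 0.11; median-of-ratios scaling set it to 0.00, gave 52.1% higher, and ended the call of the cytosolic ribosomal proteins (adjusted p = 0.0684). In that list 23 of 44 measured members rose, 1 fell and 20 did not pass (33 rose and 1 fell adjusted over the list alone; median 0.22, adjusted p = 9.72e-06, and adjusted p = 0.359 with an estimated correlation) before the change of scaling. Without 1343KO day 16 replicate 2 the count was 2906.

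**Figure D3:**
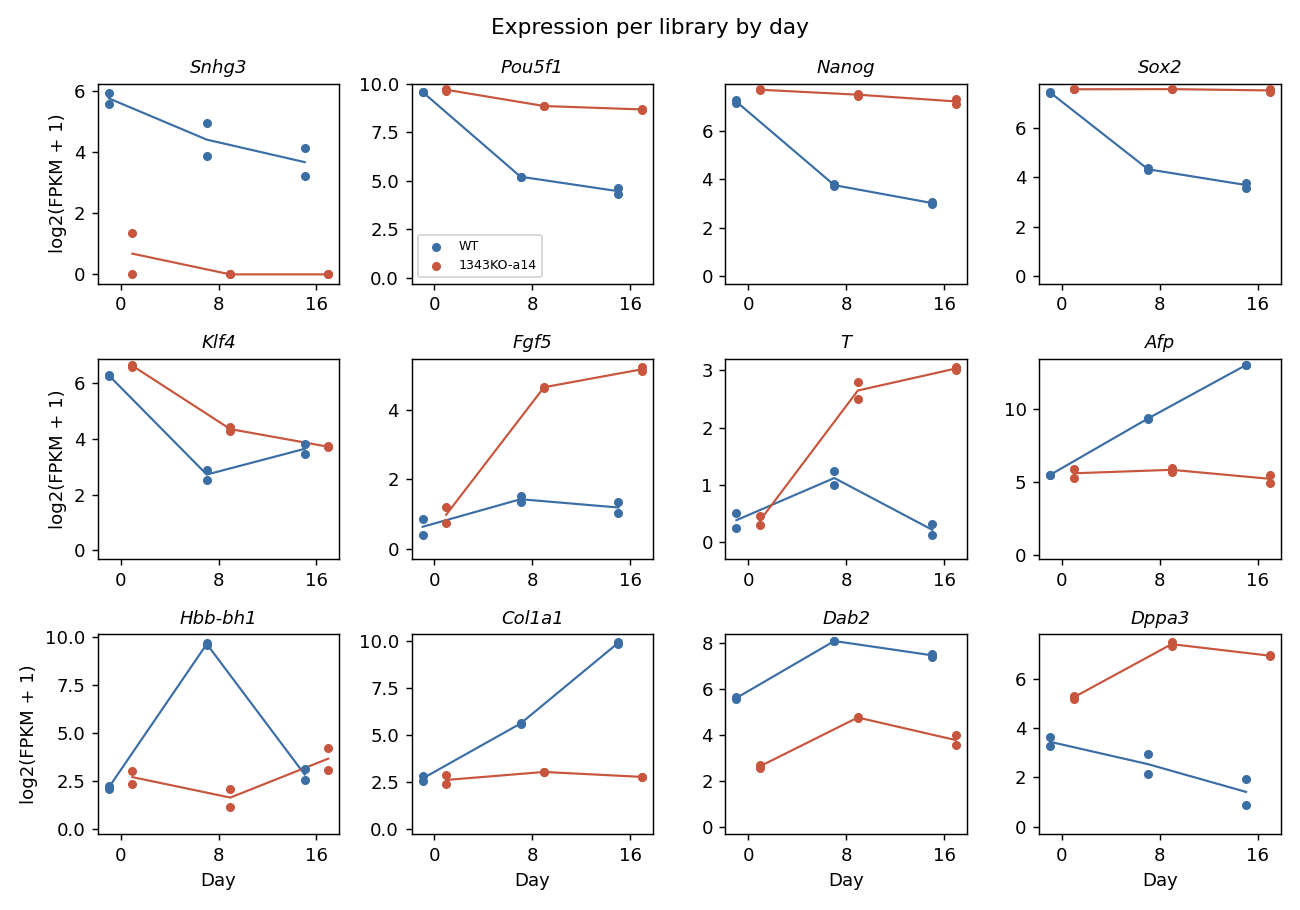
Level of 12 genes on a log2(FPKM + 1) axis against day of culture (0, 8 and 16) in WT and the 1343KO line; points are single libraries, 2 per group, and lines join the group means. Pou5f1, Nanog and Sox2 end at 21.1, 7.14 and 11.9 FPKM in WT and at 408, 149 and 182 in the 1343KO line.

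Between the lines at day 8, pluripotency genes were higher and yolk sac, blood, mesoderm and matrix genes lower in the 1343KO line. Pou5f1 was at 461 ± 10.8 against 35.9 ± 0.401 FPKM in WT (SD, n = 2; log2 change 3.65 ± 0.09 (SE), adjusted p = 2.95e-08), Nanog at 180.4 ± 6.86 against 12.6 ± 0.385 (3.74 ± 0.08) and Dppa3, a germ cell and naive state gene, at 167 ± 11.1 against 5.02 ± 2.26 (4.86 ± 0.33). Hbb-bh1 was at 2.23 ± 1.44 against 802 ± 59.9 (log2 change -8.03 ± 0.41 (SE), adjusted p = 1.04e-06). In the naive list 19 of 20 measured members were higher and 1 was lower (median 3.57, adjusted p = 5.38e-14); the 1 lower was Tbx3 (-1.56), also a mesoderm factor. In the general pluripotency list 13 of 14 measured members were higher and 1 was lower (median 2.77, adjusted p = 9.97e-11), with Tdgf1 (3.68) and Sox2 (3.24) higher and the RNA-binding protein gene Lin28a lower (-0.57). In the formative list 11 of 14 measured members were higher and 3 did not pass (median 2.11, adjusted p = 4.12e-07), as in the methyltransferase Dnmt3b (2.12) and Fgf5 (3.24 ± 0.22). All 16 blood genes were lower (median -2.64, adjusted p = 9.6e-11), including the alpha globin Hba-a1 (-5.82), whose near-identical copy can share its reads. In the extraembryonic endoderm list 18 of 19 measured members were lower and 1 did not pass (19 lower adjusted over the list alone; median -2.97, adjusted p = 4.06e-16), led by Rbp4 (-4.86 ± 0.16), Apob (-4.17) and Ttr (-3.86). In general mesoderm 12 of 15 measured members were lower and 3 did not pass (median -2.53, adjusted p = 1.76e-08), with Hand1 (-3.21) and Hand2 (-3.73), and in endothelium 1 of 15 measured members was higher, 11 were lower and 3 did not pass (median -2.17, adjusted p = 1.56e-05), with Cdh5 (-2.97) lower and the junction gene Pecam1 higher (0.80).

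At day 8 in the list of homeobox cluster genes, which pattern the body axis, 15 of 18 measured members were lower and 3 did not pass (16 lower adjusted over the list alone; median -1.82, adjusted p = 1.91e-07), with Hoxc8 (-3.41 ± 0.21) in front. In the ribosome biogenesis list 32 of 35 measured members were higher and 3 did not pass (median 0.96, adjusted p = 2.64e-14), led by Ncl (458 ± 3.21 against 219 ± 9.51; 1.06 ± 0.05). In the list of cytosolic ribosomal proteins, many of which have pseudogenes that can share reads, 40 of 44 measured members were higher and 4 did not pass (median 0.48, adjusted p = 5.38e-14, and adjusted p = 0.192 with an estimated correlation). In the cardiac list 2 of 18 measured members were higher, 8 were lower and 8 did not pass (median -0.64, adjusted p = 0.027, and adjusted p = 0.191 with an estimated correlation), with Tnnt2 lower (-2.34), and the list did not pass with TPM scaling (adjusted p = 0.105). T (1.53 ± 0.20) and Eomes (0.83 ± 0.23) were higher while the streak list had 3 higher, 3 lower and 2 not passing (adjusted p = 0.927). Gata4 (-2.30), Gata6 (-2.44), Foxa2 (-1.59), Afp (-3.52) and Kdr (-3.12) were lower, Klf4 (1.63) and Pax6 (0.95) higher, and Sox17 differed by -1.06 without passing (adjusted p = 0.0891; 0.00692 without 1343KO day 0 replicate 1, 0.00721 without replicate 2 and 0.00797 on the 4 libraries of that day). In total 6973 genes passed (3788 higher, 3185 lower; limma, Benjamini-Hochberg), 1494 and 1510 by at least 2-fold, with 21 of 39 lists, 11 of them with an estimated correlation. With TPM scaling 2834 were higher and 4075 lower, so that the higher share went from 54.3% to 41.0%. With median-of-ratios scaling 3390 were higher and 3534 lower. Eomes lost its call without WT day 8 replicate 1 (adjusted p = 0.121) or 1343KO day 8 replicate 1 (0.112) and with only the 4 libraries of that day (0.116). Pax6 lost its call without 1343KO day 8 replicate 1 (0.0541). The chromosome 8 median was -0.41 beside these groups, and 6605 genes passed without chromosomes 8 and Y.

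At day 16 the 1343KO line had higher pluripotency genes than WT and lower plasma protein, collagen and macrophage genes. Pou5f1 was at 408 ± 15.4 against 21.1 ± 3.5 FPKM (SD, n = 2; log2 change 4.22 ± 0.09 (SE), adjusted p = 5.68e-09), Sox2 at 182 ± 13.3 against 11.9 ± 1.27 (3.83 ± 0.08) and Fgf5 at 35.5 ± 1.99 against 1.29 ± 0.372 (adjusted p = 7.62e-07). Afp was at 36.3 ± 9.63 against 8193 ± 75.8 (log2 change -7.81 ± 0.21 (SE), adjusted p = 1.58e-08) and Col1a1 at 5.78 ± 0.0335 against 978 ± 57.5 (-7.17 ± 0.15). In the naive list 18 of 20 measured members were higher and 2 did not pass (median 3.53, adjusted p = 2.48e-11), led by Dppa4 (4.62), Nanog (4.20) and Zfp42 (4.18); Klf4 differed by 0.08 (adjusted p = 0.696). In the general pluripotency list 13 of 14 measured members were higher and 1 did not pass (median 3.10, adjusted p = 1.86e-11), and in the formative list 13 of 14 measured members were higher and 1 did not pass (median 2.62, adjusted p = 3.86e-08). All 19 extraembryonic endoderm genes were lower (median -5.54, adjusted p = 1.16e-16), as were all 15 macrophage genes (median -4.24, adjusted p = 1.86e-11), such as Mrc1 (-4.26 ± 0.16) and the complement gene C1qc (-5.46). In the fibroblast and matrix list 17 of 18 measured members were lower and 1 did not pass (median -4.88, adjusted p = 1.74e-14), with Col1a2 (-6.69) and Lum (-6.14). In general mesoderm 14 of 15 measured members were lower and 1 did not pass (median -1.63, adjusted p = 1.1e-06) and in endothelium 12 of 15 measured members were lower and 3 did not pass (median -1.63, adjusted p = 3.75e-06).

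Ribosome biogenesis and cell division genes were higher at day 16 in the 1343KO line. All 35 ribosome biogenesis genes were higher (median 1.62, adjusted p = 5.08e-17), with Ncl at 455 ± 2.49 against 161 ± 1.37 (1.49 ± 0.05). All 20 cell division genes were higher (median 1.21, adjusted p = 4.33e-10), led by Plk1 (1.46 ± 0.07), and in the DNA replication list 17 of 18 measured members were higher and 1 did not pass (median 1.44, adjusted p = 4.81e-09), led by Rrm2, which makes deoxynucleotides (1.70). All 44 cytosolic ribosomal proteins were higher (median 0.82, adjusted p = 5.08e-17, and adjusted p = 0.134 with an estimated correlation). T (2.83 ± 0.20) and Eomes (2.43 ± 0.23) were higher, while the streak list did not pass (adjusted p = 0.152). The cardiac list had 4 higher, 5 lower and 9 not passing (adjusted p = 0.875), with Actc1 higher (0.96) and Tnnt2 lower (-0.79). In the blood list 8 of 16 measured members were lower and 8 did not pass (median -0.95, adjusted p = 0.0137, and adjusted p = 0.0703 with an estimated correlation). Hbb-bh1 differed by 0.83 (adjusted p = 0.122). Gata4 (-1.07), Gata6 (-2.23), Foxa2 (adjusted p = 0.0035) and Kdr (-1.63) were lower, Esrrb (4.39) and Pax6 (1.32) higher, and Sox17 (-0.76) did not pass (adjusted p = 0.19; 0.0243 without 1343KO day 0 replicate 1 and 0.0251 without replicate 2). In total 8570 genes passed (4639 higher, 3931 lower), 2088 and 2287 by at least 2-fold, with 20 lists, 13 of them with an estimated correlation. With median-of-ratios scaling 3915 were higher and 4543 lower, and with TPM scaling 4011 and 4395, so the majority depended on the scaling. Tnnt2 lost its call without WT day 16 replicate 2 (adjusted p = 0.208) or 1343KO day 16 replicate 2 (0.159), without a filter (0.055), with a pseudocount of 0.1 (0.17) and with only the 4 libraries of that day (0.118). Hbb-bh1 passed without 1343KO day 16 replicate 1 (0.0251). The chromosome 8 median was -0.35 beside these groups, and 8164 genes passed without chromosomes 8 and Y.

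**Figure D4:**
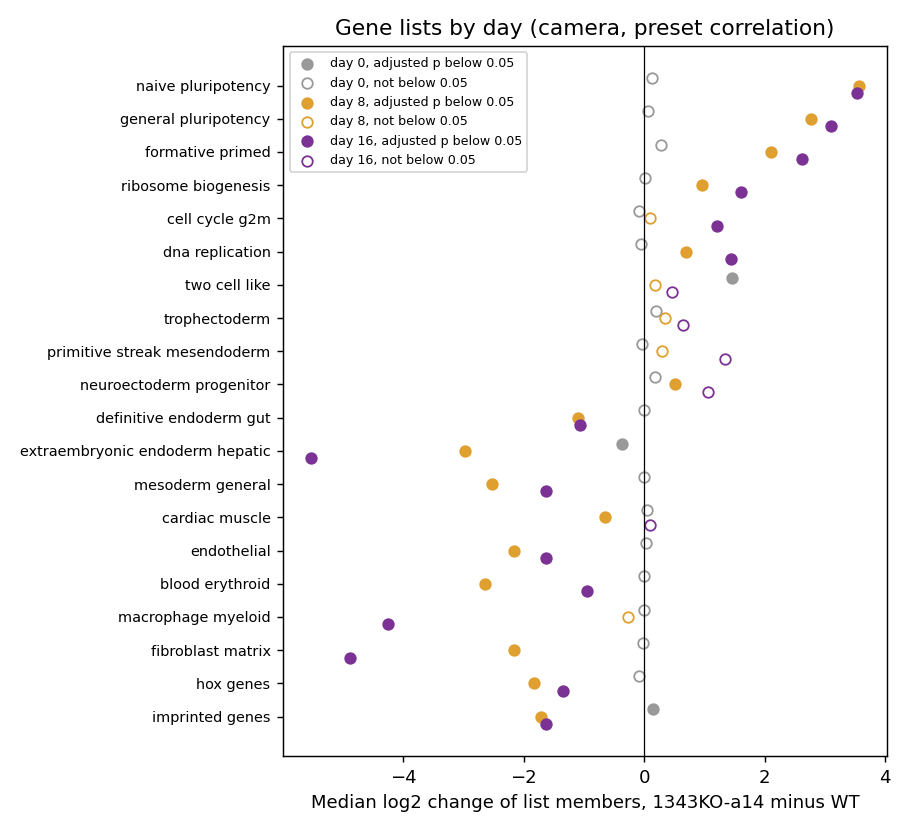
Median log2 difference (1343KO minus WT) of the members of 20 gene lists, with 1 colour per day; each point is 1 list on 1 day, and filled points passed the list test at an adjusted p under 0.05. Extraembryonic endoderm genes lie at -2.97 and -5.54 on days 8 and 16, and naive pluripotency genes at 3.57 and 3.53.

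Whether the change since day 0 differed between the lines was tested by interaction. The difference of changes (1343KO minus WT) for Pou5f1 was 3.53 ± 0.13 at day 8 and 4.10 ± 0.13 at day 16 (SE; adjusted p = 6.95e-07 and 1.58e-07), for Hbb-bh1 -8.57 ± 0.58 at day 8 and for Afp -7.91 ± 0.30 at day 16. Of genes that rose at least 2-fold in WT by day 16 (3539), the median change was 1.74 in WT and 0.57 in the 1343KO line, and by the interaction test 2392 changed less upward in the 1343KO line and 20 more. For the 2487 that fell at least 2-fold, the medians were -1.45 and -0.33, with 1933 that changed less downward and 6 more. At day 8 the medians were 1.56 and 0.54 for the 2476 genes that rose and -1.41 and -0.41 for the 1798 that fell. These genes were chosen on the WT change, which by itself favours a smaller value in the other line. At day 16 in the naive list 18 of 20 measured members moved up relative to WT and 2 did not pass (median 3.40, adjusted p = 1.53e-12). In the ribosome biogenesis list all 35 measured members moved up relative to WT (median 1.62, adjusted p = 1.97e-18). In the extraembryonic endoderm list 2 of 19 measured members moved up relative to WT, 14 moved down relative to WT and 3 did not pass (median -5.52, adjusted p = 7.16e-10), with the laminin Lama1 (1.22) and the endoderm factor Sox7 (1.07) against the rest. Lama1 and Sox7 started low in the 1343KO line, at 0.216 and 0.103 of the WT level at day 0, and were still lower than WT at day 16. In total 4605 genes passed at day 8 (2534 higher, 2071 lower) and 6512 at day 16 (3540 higher, 2972 lower), with 21 lists on each day, 11 and 13 of them with an estimated correlation. The majority turned with TPM scaling (1806 higher and 2623 lower at day 8, 3031 and 3228 at day 16) and with median-of-ratios scaling (2196 and 2303, 2941 and 3419).

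Averaged over the 3 days, 4.06 ± 0.19 for Dppa3, 3.14 ± 0.06 for the ES cell noncoding RNA Lncenc1 and 2.91 ± 0.07 for Esrrb were among the 10 widest upward differences of the 1343KO line, and Snhg3 (-4.40 ± 0.28), Nnat, an imprinted neuronal gene (-3.91 ± 0.12), and Afp (-3.74 ± 0.12) among the 10 widest downward. Pou5f1 (2.66) and Nanog (2.81) were higher, and Gata6 (-2.32) and Sox17 (-1.43) lower. In total 8890 genes passed, 4731 of them higher, and 20 lists, 14 with an estimated correlation. With median-of-ratios scaling 4152 were higher and 4644 lower, and with TPM scaling 3863 and 4855. The lines also differed on each day in their Y-linked and chromosome 8 genes, so genotype, clone and these chromosomes went together in every comparison between the lines.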

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

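The tests of chromosome 8 copy number and scaling, of a mixture of cells and of gene dosage were chosen only after the results were seen. So were those of a clone difference and of the endoderm genes. The criterion of the GC content test was written before its own result, but for a pattern already found in the data. The test of other splits of the libraries was set beforehand. Interaction tests found 4605 genes and 21 lists whose change from day 0 to day 8 differed between the lines, and 6512 genes and 21 lists at day 16. The differences below are the 1343KO change minus the WT change on the log2 scale. At day 8 they were above 0 for Pou5f1 (3.53), Sox2 (3.11), Nanog (3.24), Zfp42 (3.66), Esrrb (4.16), Klf4 (1.28), T (1.54), Eomes (1.53), Fgf5 (2.89) and Rcc1 (1.53), and below 0 for Afp (-3.63), Tnnt2 (-2.23), Kdr (-3.38) and Hbb-bh1 (-8.57). At day 16 they were above 0 for Pou5f1 (4.10), Sox2 (3.70), Nanog (3.71), Zfp42 (4.14), Esrrb (4.31), T (2.83), Eomes (3.14), Fgf5 (3.65), Gata4 (1.57) and Rcc1 (2.30), and below 0 for Afp (-7.91), Kdr (-1.89) and Nes (-0.70). Gata4 was lower in the 1343KO line than in WT at day 0 (-2.64) and still lower at day 16, so its value above 0 reflects the low start. For all days together, 1 of 100 splits of the genotype labels within days, the real one, gave as many genes (8890). The highest other gave 8573, with the labels of day 0 exchanged and those of days 8 and 16 kept. The real labels thus gave the largest count of the splits run. With 1 clone and replicates not known to be separate cultures, the splits cannot exclude chance differences between cultures or clones.

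Smaller changes since day 0 in the 1343KO line could come from cultures that mix cells still as in WT day 0 with cells as in WT of the same day. One proportion would then explain genes that fell and genes that rose. The day 0 fraction at day 16 was 0.606 from genes that fell in WT (quartiles 0.448 and 0.790) and 0.878 from genes that rose (0.744 and 0.967). Their difference was 0.272, against a gap of 0.0094 between libraries. These genes passed in WT with a log2 change of at least 2 and at least 20 FPKM where they were high. That choice used WT values that also enter the fraction. It can push the estimates apart, and the gap does not cover it. Single marker genes also spread widely, from 1.07 for Sox2 to 0.0089 for Klf4. For these markers the values argue against a mixture of exactly these WT states as the whole cause. A mixture that includes undifferentiated cells unlike those of WT day 0 was not tested. Direct dosage of genes on chromosomes 8 and Y would make calls between the lines gather there. At day 0, 16.4% of the 789 tested genes on these chromosomes and 3.07% of the others passed between the lines. At day 16 the interaction passed for 39.9% and 40.0%, a ratio of 1.00 (95% interval 0.917 to 1.09, with genes taken as independent). A shift of these genes that was alike on all days cancels from the interaction, so this ratio cannot decide on direct dosage. Indirect effects were not tested. The ratio replaced a first criterion, the count of calls elsewhere, which the small number of genes on these chromosomes fixed. The effect of the lesion and a clone difference other than the targeted lesion cannot be told apart, because 1 clone of the line was analysed, and a slower course was not tested.

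Set against the mean of their day, genes on chromosome 8 were lower in all 6 libraries of the 1343KO line than in any of the 6 WT libraries. An exact permutation within days (216 permutations) gave a two-sided p = 0.00926, the smallest it can give. Chromosome 8 was picked after its values were seen, and this p is not adjusted for the choice among chromosomes. Libraries of a line repeat the same difference between lines, so they are not independent units of genotype. Scaling cancels in the comparison with other chromosomes, and the day 0 value of -0.42 lay outside the other chromosomes' range of -0.03 to 0.03. The values of days 8 and 16 (-0.41 and -0.35) lay outside wider ranges, of -0.22 to 0.09 and -0.23 to 0.10. Against genes matched on GC content and level the day 0 value was -0.40. The tables thus argue against scaling, GC content and level as the whole cause. A difference in chromosome 8 copy number between the cultures predicts a shift along the whole chromosome, and at day 0 all 10 windows lay below every other chromosome's median; 2 copies against 3 in every cell would give -0.58, and a copy gained in WT or lost in the 1343KO line gives the same sign, so this stays a candidate explanation. The criteria of the window and scaling tests were reset after a first result: the windows were first asked to lie below 0 on all days, where 19 of 20 later ones did (the exception, 71592176 to 80739497 at day 16, was at 0.09), and the scaling test first asked for a gap wider than the other chromosomes' range, which days 8 and 16 missed.

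Extraembryonic endoderm genes were lower in the 1343KO line at day 0. Direct dosage of chromosome 8 genes is not the whole cause, since the list's median without chromosomes 8 and Y was -0.33 and the list was still called. Indirect effects of a chromosome 8 difference on genes elsewhere were not tested. A larger share of endoderm-like cells in the WT cultures could set all called members apart by a like factor; the highest ratio of 1343KO to WT level (Lamb1, 0.526) was 5.60 times the lowest (Cubn, 0.0939). A background level in the other cells would also spread these ratios, so this and a lower level per cell cannot be told apart from RNA of whole cultures.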

How the results depend on the processing

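Leaving out chromosomes 8 and Y was the setting chosen after the results were seen. No call of a named gene or list turned direction in any setting. Besides fixed markers, the genes compared were mainly picked in the same data for the largest changes or smallest p. Their calls were thus likely to hold, and the numbers below do not measure how stable calls are in general. Many left-out libraries also belong to groups outside the contrast and alter only the pooled spread. Of comparisons of a gene with its value under another setting, leaving out 1 library left direction and side of the threshold as they were in 19436, ended the call in 729 and added one in 19. For other settings these were 13104, 295 and 11, and for lists 4588, 48 and 44 (libraries) and 1813, 111 and 26 (other settings). Counts of genes over all left-out libraries ranged, for 1343KO against WT, from 203 to 513 at day 0, 5449 to 6939 at day 8, 7284 to 8569 at day 16 and 8278 to 8484 over all days; for WT from 6932 to 8305 at day 8 and 8730 to 9955 at day 16; for the 1343KO line from 2480 to 3633 and 2906 to 4286; and for the interaction from 3607 to 4478 and 5599 to 6456. A lone library was assumed to vary like the other groups. Lists called between the lines ranged from 6 (without 1343KO day 0 replicate 1) to 12 at day 0, 20 to 21 at day 8 and 20 to 22 at day 16. With a log2 change of at least 1, the counts between the lines were 194, 3004, 4375 and 1657 (days 0, 8, 16 and all), in WT 4274 and 6026, in the 1343KO line 1330 and 1633, and for the interaction 2625 and 4121. On each day's 4 libraries alone limma called 0 genes at day 0 (2489 at an unadjusted p under 0.05), 5815 at day 8 and 7691 at day 16; fewer libraries leave fewer degrees of freedom. With an estimated correlation 2, 11 and 13 lists passed between the lines at days 0, 8 and 16, against 10, 21 and 20. At day 0 other settings gave 618 genes (pseudocount 0.1), 546 (no filter), 601 (mean of at least 5 FPKM), 602 (robust), 609 (median-of-ratios) and 610 (TPM).

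The replicate number as a block, though deviations of libraries with the same number did not correlate (-0.04 to 0.04 over 15 pairs of groups, 0 above 0.1), gave 478, 6902, 8522 and 8853 genes between the lines, 8294 and 9924 in WT, 3696 and 4276 in the 1343KO line and 4501 and 6420 for the interaction, with 11, 20 and 20 lists between the lines. A lack of correlation cannot exclude that a number follows 1 culture through time, since noise of single libraries could hide it. The main fit did not pair libraries by number. At about 4885000 to 8047000 fragments, genes near 1 FPKM rest on few fragments, and a 2-fold change was recovered for 65% of simulated genes at day 0, so a gene that did not pass can still differ; 407 genes passed at day 0 without chromosomes 8 and Y.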

Other observations

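Prl3b1, Prl4a1 and the test of day 16 against day 8 were chosen only after the results were seen. Prl2a1, a prolactin family member of the placenta, was at 18.1 ± 2.46 FPKM (SD, n = 2) in the 1343KO line at day 16 after 0.322 and a listed 0 in the day 0 libraries (adjusted p = 0.00045), and at 1.01 and 1.66 in the WT day 16 libraries. Ctsj, a placental cathepsin, was at 17.6 ± 2.44 against 2.05 ± 1.09 in WT at day 16. Prl3b1 and Prl4a1, of the same family, were at 10.7 ± 0.0844 and 5.87 ± 0.881, and Tpbpa, a spongiotrophoblast gene, at 5.53 ± 1.29 against 1.09 ± 0.0819 in WT at day 16. Near-identical members of this family can share reads. The trophectoderm list as a whole did not pass between the lines at day 16 (camera, adjusted p = 0.0956). Of its members 7 were higher, 3 lower and 3 did not pass (8 higher and 3 lower adjusted over the list alone). The lower ones were Hand1 (-1.57), Krt7 (-1.61) and Cdx2 (-1.11). Other lineages also express these genes, as they do Eomes, which was among the higher ones.

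By day 16 in WT 21 of 24 measured members rose, 1 fell and 2 did not pass (median 2.72, adjusted p = 4.46e-09) in the list of imprinted genes, with Igf2, a foetal growth factor, going from 48.8 ± 3.94 to 3496 ± 27.1 FPKM (SD, n = 2) and Peg10 (3.47), Peg3 (4.75) and H19 (4.94) at the lowest p and the splicing protein gene Snrpn lower (-1.91). In the 1343KO line 18 of 24 measured members rose, 1 fell and 5 did not pass (median 0.96, adjusted p = 1.18e-07), with Phlda2 lower (-1.21), and Igf2 reached 433 ± 0.79. Of the same list between the lines at day 16, 1 of 24 measured members was higher, 20 were lower and 3 did not pass (median -1.62, adjusted p = 2.35e-09); the 1 higher was Snrpn (2.68), which overlaps Snurf, so reads can be shared. In the interferon response list, also between the lines at day 16, 1 of 14 measured members was higher, 8 were lower and 5 did not pass (1 higher and 9 lower adjusted over the list alone; median -1.14, adjusted p = 0.00137, and adjusted p = 0.0937 with an estimated correlation), with Ifit3 (-3.31 ± 0.24) and Ifit1 (-2.14) lower and the membrane protein Ifitm3 higher (0.95). In the 1343KO line by day 16, 2 of 18 measured members rose, 9 fell and 7 did not pass (2 rose and 10 fell adjusted over the list alone; median -0.56, adjusted p = 4.37e-05) in the list of stress and unfolded protein genes, led by the serine synthesis enzyme Psat1 (-1.73 ± 0.07) and its regulator Atf4 (-0.61), with the chaperone genes Dnajb1 (0.43) and Dnajb9 (0.47) higher. Dnajb1 did not pass without 1343KO day 0 replicate 2 (adjusted p = 0.0695) or day 16 replicate 1 (0.0697), or with median-of-ratios scaling (0.0503). Dnajb9 did not pass without 1343KO day 0 replicate 1 (0.104) or 2 (0.157), day 8 replicate 1 (0.0554) or 2 (0.0557), or day 16 replicate 2 (0.234), nor without WT day 8 replicate 1 (0.0562) or 2 (0.0565) or day 16 replicate 1 (0.0554) or 2 (0.0549). Its adjusted p was 0.13 with median-of-ratios scaling, 0.0608 with TPM scaling, 0.0674 without a filter and 0.0611 with a replicate block. In the glycolysis and hypoxia list 15 of 21 measured members rose, 1 fell and 5 did not pass (median 0.60, adjusted p = 3.66e-08, and adjusted p = 0.0586 with an estimated correlation), led by Pgk1 (1.34) and Bnip3 (1.95), with hexokinase 2, Hk2, lower (-0.52); the enzyme Aldoa is counted on 2 entries of the table.

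Between day 8 and day 16 4495 genes passed in WT (2301 higher, 2194 lower) and 131 in the 1343KO line (98 higher, 33 lower; limma, 2038 at an unadjusted p under 0.05). The difference between these counts was not tested.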
